A study of Homo sapiens with 20 samples.

How the data were processed

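Total RNA was extracted with TRIzol from cells labelled KYSE150 and was sequenced on an Illumina instrument. KYSE150 is a human esophageal squamous cell carcinoma line, grown here in RPMI-1640 with 10% fetal bovine serum. The labels give 20 libraries in 4 groups of 5, named by the title codes B2, B2PS, CC and CP. Per the labels, B2 and B2PS carry the genotype entry for overexpressed OTUB2, a deubiquitinating enzyme, and CC and CP carry the control entry. No label says which codes received soybean phosphatidylserine, the treatment named in the series title. PS is a usual abbreviation of that lipid, but the labels do not spell it out, so the codes are kept as names. The labels also do not say whether the 5 libraries of a group came from separate cultures.

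The deposited table holds raw counts per gene and library, and the authors' FPKM values beside them. HISAT2, DESeq and the genome build GRCh38 are listed by the submitters without versions. The counting tool, the annotation release and the strand setting are not given in the sources used here. The table has 59925 genes, of which 58676 have Ensembl identifiers. All 58676 identifiers were found with the same symbol in GENCODE release 29, which supplied positions and biotypes. The other 1249 entries are transcribed features that the authors named with no gene symbol, and 684 of them were tested. The deposited counts were used for every result. The deposited FPKM values were used only to check that counts, FPKM and library totals implied the same gene length in every library, within a coefficient of variation of 1 percent, which held for 19718 of 19718 genes with values in at least 2 libraries.

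Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18188 genes holding 99.8% to 99.9% of each library's counts. One model with the 4 groups as its only term was fitted to all 20 libraries after TMM scaling, with 16 residual degrees of freedom. The quasi-likelihood F test, two-sided, gave the p-values, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18188 genes of a comparison. Adjusted p-values of single genes below are from this edgeR test unless another tool is named. Library totals ran from 11454785 to 18546145 counts, so that 1 count is 0.0539 to 0.0873 CPM, the count per 1e6 of the library. CPM values below are scaled by TMM and given as mean ± SD over 5 libraries. A group without counts was set at a floor of 3 counts over the group, and with 1 to 3 counts only the CPM values are given or a ratio with its 95% counting interval. Such floors and intervals cover counting error only, since reads carry no molecular identifiers.

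The pairwise comparisons were B2 with CC and B2PS with CP, which differ in genotype label, and CP with CC and B2PS with B2, which differ in title code within a genotype label. The interaction compared the last pair, as B2PS minus B2 less CP minus CC. The comparisons, tests, gene lists, named-gene rule and all alternatives but 1 were chosen before the data were examined. Genes are named by that rule. OTUB2, CALML3, OTUB1, PTDSS1 and PTDSS2 are always named. Some genes that the rule names are not reported here. For each pairwise comparison the 10 largest rises and 10 largest falls are named, among called genes whose groups do not overlap and whose mean log2 CPM is at least 1. Each list contributes up to 4 called members with the largest change, or its 2 most expressed members where none is called.

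A total of 34 gene lists was fixed. They cover interferon response, antigen presentation, phosphatidylserine and phospholipid synthesis, phosphatidylserine exposure, nuclear and mitochondrial respiratory chain genes, glycolysis, the tricarboxylic acid cycle, cholesterol and fatty acid synthesis, endoplasmic reticulum chaperones, ATF4 targets, hypoxia, the G1/S and G2/M phases, and targets of p53, NF-kappaB, NRF2 and YAP. They also cover immediate early genes, extracellular matrix, squamous differentiation, basal squamous identity, cytosolic ribosomal proteins, ribosome biogenesis, lysosome, heat shock, metallothioneins, apoptosis, histones (as a sign of how RNA was selected), nuclear retained RNAs (as a sign of RNA quality), and markers of fibroblasts, leukocytes and endothelium. The 32 lists with at least 5 tested members were tested against all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, adjusted over the 32 lists. The test was run again with an estimated correlation, and fry was run as a test of whether members move on balance in 1 direction. Counts of called members are given over all genes and adjusted over the list alone.

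Alternatives were RLE scaling, library size only, no filter, a stricter filter (CPM of at least 1 in at least 5 libraries), the replicate number as a block, a fit of only the compared groups, limma-voom, DESeq2 1.42.0, an adjusted p under 0.01, a 2-fold minimum, Spearman rho for correlations, and each library left out in turn. Thinning every library to the smallest total was added after seeing the data. Library measures were compared by exact permutation tests. The whole procedure was tested on simulated data with 50 seeded genes for each size of change. A 4-fold change was recovered for 96.0% to 100% of seeded genes and a 2-fold change for 68.0% to 96.0%, with 7 to 11 false calls per comparison among 17777 to 17916 genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.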

Results

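RNA of cells labelled KYSE150, an esophageal squamous carcinoma line, was counted in 20 libraries. Each of the title codes B2, B2PS, CC and CP had 5 libraries. Library totals ran from 15285042 to 17435953 counts in B2, from 16471424 to 18546145 in B2PS, from 11454785 to 14681516 in CC and from 13145815 to 15427643 in CP. Totals differed between genotype labels in both code pairs (exact permutation test, two-sided, p = 0.00794, the smallest possible; adjusted p = 0.0190 over 24 library tests). CPM values are given as mean ± SD of n = 5 libraries. The mean number of genes with a count was 24938 in B2, 25302 in B2PS, 25940 in CC and 26651 in CP. Genotype label separated the libraries along a first principal component that held 90.4% of the variance. Pearson r between libraries across genes was 0.974 to 0.993 within a genotype label and 0.771 to 0.806 between the labels. The biological coefficient of variation was 0.137. No pair of replicates was a repeated library, since the chi-square per gene of the 40 pairs was 5.29 to 53.7. A value of 1 is expected of the same library sequenced again, and an identical copy would give less.

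The genotype labels were first compared with the level of OTUB2 itself (ENSG00000089723, chromosome 14, 94026329 to 94048930, GRCh38), the deubiquitinating enzyme named in the series. OTUB2 was not higher in libraries labelled as overexpressing it. Its level was 1.72 ± 0.325 CPM in B2 and 2.50 ± 0.525 CPM in CC (log2 fold change -0.53, SE 0.23, adjusted p = 0.0443, 95% interval -1.02 to -0.05). It was 2.33 ± 0.377 CPM in B2PS and 2.75 ± 1.10 CPM in CP (log2 fold change -0.24, SE 0.22, adjusted p = 0.337, 95% interval -0.70 to 0.22). These levels rest on 22 to 67 counts per library. Over 19 alternatives the B2 and CC difference stayed between -0.65 and -0.41 with adjusted p from 0.0221 to 0.137, and 10 of the 19 called it. Its call was lost when any of B2-1 (adjusted p = 0.0717), B2-2 (0.0956), B2-3 (0.0942), B2-5 (0.104), CC-1 (0.0527), CC-3 (0.0757) or CC-4 (0.137) was left out. Without CP-4, which had 4.59 CPM, the B2PS and CP difference was 0.03 (adjusted p = 0.906). Between title codes, OTUB2 differed by 0.14 for CP against CC (adjusted p = 0.769) and by 0.44 for B2PS against B2 (adjusted p = 0.783). A transgene with an altered coding sequence would not be counted here, so B2 and B2PS are described below only as libraries labelled OTUB2-overexpressing. Cells of a different origin or clone under the genotype labels also remain open, so the differences below are not ascribed to OTUB2.

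**Figure D1:**
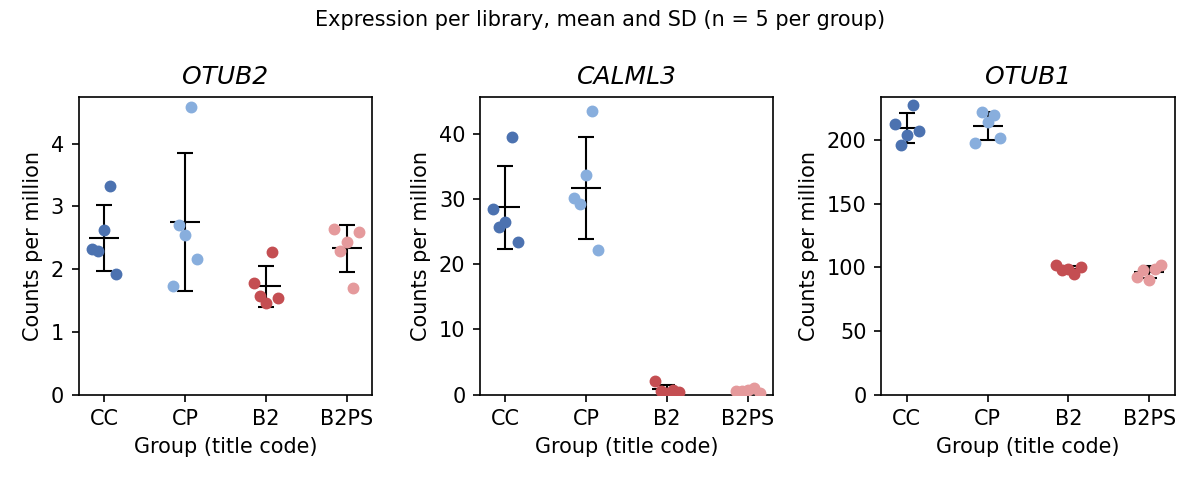
Expression of OTUB2, CALML3 and OTUB1 in TMM-scaled CPM on a linear axis from 0, with 1 point per library and the mean ± SD of each group of 5. CALML3 and OTUB1 were lower in B2 and B2PS than in CC and CP, while OTUB2 was not higher in B2 (1.72 ± 0.325 CPM) than in CC (2.50 ± 0.525 CPM).

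Comparing B2 with CC asks what differs between cells labelled OTUB2-overexpressing and control cells, with the title codes B2 and CC. By the set test, interferon response (38 of 42 members fell), antigen presentation (28 of 34) and squamous differentiation genes (50 of 54) were lower in B2. Glycolysis (16 of 23 rose, 4 fell) and G1/S genes (27 of 39 rose, 1 fell) were higher, and no list passed with an estimated correlation (lowest adjusted p = 0.524). CALML3 (ENSG00000178363, chromosome 10, 5524009 to 5526771), a calmodulin-like protein of squamous epithelium, was 0.804 ± 0.734 CPM in B2 and 28.7 ± 6.32 CPM in CC (log2 fold change -5.16, SE 0.32, adjusted p = 6.8e-13). OTUB1 (ENSG00000167770, chromosome 11, 63985853 to 64001811), the paralog of OTUB2, was 98.7 ± 2.68 and 209 ± 11.7 CPM (log2 fold change -1.09, SE 0.06, adjusted p = 1.3e-13). PTDSS1 (ENSG00000156471, chromosome 8, 96261715 to 96336995) and PTDSS2 (ENSG00000174915, chromosome 11, 448268 to 491399), the phosphatidylserine synthases, did not pass the test, with log2 fold changes of -0.04 ± 0.08 (SE; adjusted p = 0.632) and 0.03 ± 0.08 (adjusted p = 0.719).

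The 10 largest falls in B2 were of genes abundant in CC. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), an inhibitor of thioredoxin and glucose uptake, had 0 counts in B2 and 2690.0 ± 333 CPM in CC, at least 76005-fold lower. GABRP, EFEMP1, SPTSSB and SPRR2E also had 0 counts in B2. Their CC levels were 369 ± 49.5, 256 ± 34.1, 147 ± 34.6 and 129 ± 81.7 CPM, so that they were lower by at least 10434-fold, at least 7238-fold, at least 4146-fold and at least 3653-fold. S100A7, the psoriasin gene of differentiating keratinocytes, had 1 count over all B2 libraries and 663 ± 510.0 CPM in CC. GJB6, a gap junction connexin, and PIGR, the polymeric immunoglobulin receptor, also had 1 count in B2, against 462 ± 125 and 274 ± 42.9 CPM in CC. SOSTDC1, a secreted antagonist of BMP signalling, had 2 counts in B2 against 991 ± 70.8 CPM in CC. KRT1, a keratin of suprabasal cells, was 0.140 ± 0.280 CPM in B2 and 2885 ± 1208 CPM in CC (log2 fold change -14.24, SE 0.51, adjusted p = 3.5e-17). The 10 adjusted p-values lay between 9.8e-22 and 5.8e-08. The sources do not say how reads shared between paralogs, such as the SPRR2 genes, were counted.

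The 10 largest rises were of genes with at most 3 counts over all CC libraries. MAGEA12 (ENSG00000213401, chromosome X, 152733779 to 152737669), a cancer-testis antigen, had 77.5 ± 14.9 CPM in B2 and 0 counts in CC, at least 1656-fold higher. SLC20A2 (ENSG00000168575, chromosome 8, 42416475 to 42541926), a phosphate transporter, had 74.7 ± 5.78 CPM and 0 counts, at least 1596-fold higher. The transcription factor genes ZNF680, ZFP30 and FOXR2 and the zinc finger gene ZC4H2 had 33.2 ± 7.71, 18.4 ± 4.79, 20.9 ± 1.90 and 15.7 ± 2.14 CPM in B2 and 0 counts in CC. ZBED9 (19.5 ± 3.13 CPM), the noncoding LINC02582 (20.4 ± 7.46 CPM) and the pseudogene PSPHP1 (24.4 ± 6.62 CPM) likewise had 0 counts in CC. FKBP10, an endoplasmic reticulum prolyl isomerase, had 145 ± 13.3 CPM in B2 and 3 counts over all CC libraries. The 10 adjusted p-values lay between 1.6e-20 and 6.5e-12. PSPHP1 and MAGEA12 have close relatives in the genome, and how reads shared with them were counted is not given.

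Among the lists lower in B2, the interferon list had 38 of 42 tested members that fell and 3 that rose (median -1.72, adjusted p = 6.3e-19, and 0.524 with an estimated correlation). IFI27 (-9.57), MX2 (-8.83) and EPSTI1 (-8.61, log2 fold changes) were among them, and CMPK2 had 1 count in B2 against 64.1 ± 9.87 CPM in CC. Of the antigen presentation genes, 28 of 34 fell and 5 rose (median -1.63, adjusted p = 5.6e-07, and 0.806 with an estimated correlation). HLA-DRA (-11.17) and CD74 (-9.37) of the class II pathway fell, IDO1 had 0 counts in B2 and was at least 1893-fold lower, and the chemokine CXCL10 had 2 counts against 25.5 ± 6.16 CPM. Squamous differentiation genes had 50 of 54 members that fell and 1 that rose (median -5.29, adjusted p = 5.6e-12, and 0.740 with an estimated correlation), including S100A7, KRT1, SPRR2E and SPRR2D, the last with 0 counts in B2 and 100.1 ± 77.5 CPM in CC. The basal squamous list had 26 of 37 that fell and 8 that rose (median -0.59, adjusted p = 0.0332, and 0.876 with an estimated correlation). Its largest falls were in the tight junction gene CLDN1 (-13.50), SOX2 (-8.08), KRT19 (-4.64) and NOTCH3 (-2.70). All 13 mitochondrially encoded genes fell (median -0.98, adjusted p = 0.0135, and 0.876 with an estimated correlation), with MT-ND1 at -1.60, MT-ND6 at -1.48, MT-ND3 at -1.35 and MT-CYB at -1.30, and the mitochondrial share of counts was 3.33% ± 0.513 in B2 and 5.76% ± 1.02 in CC. Of 9 fibroblast markers, 7 fell and 1 rose (median -2.11, adjusted p = 0.0385, and 0.524 with an estimated correlation), among them DCN (-7.25), LUM (-6.24), MGP (-5.71) and COL1A1 (-2.11).

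Among the lists higher in B2, glycolysis had 16 of 23 members that rose and 4 that fell (median 0.82, adjusted p = 4.5e-04, and 0.876 with an estimated correlation). The glucose transporter SLC2A3 rose by 10.43, ENO2 by 3.49, PFKFB4 by 2.54 and PFKP by 2.44 on the log2 scale. Cholesterol synthesis had 19 of 25 that rose and 5 that fell (median 1.53, adjusted p = 0.0103, and 0.881 with an estimated correlation). Its mean was -0.03, opposite in sign to its median and test, with falls in DHCR7 (-10.65) and ACAT2 (-7.70), while IDI1 rose by 3.19. G1/S genes had 27 of 39 that rose and 1 that fell (median 0.38, adjusted p = 0.0103, and 0.959 with an estimated correlation), with MCM10 at 2.45, MCM3 at 1.63, RFC2 at 1.26 and CCNE1 at -1.21. G2/M genes had 27 of 43 that rose and 3 that fell (median 0.38, adjusted p = 0.0183, and 0.971 with an estimated correlation), with CENPF at 2.24, NUF2 at 1.17, ANLN at 1.15 and HMMR at 1.04. Ribosome biogenesis had 21 of 39 that rose and 1, MYC (-1.80), that fell (median 0.33, adjusted p = 0.0103, and 0.876 with an estimated correlation), and NOP16 (1.66), LYAR (1.51) and TCOF1 (1.48) rose. ATF4 targets had 18 of 31 that rose and 6 that fell (median 0.65, adjusted p = 0.0476, and 0.876 with an estimated correlation), with STC2 at 3.69, ATF3 at 3.32, ALDH1L2 at -4.80 and NUPR1 at -3.36. Immediate early genes had 18 of 32 that rose and 7 that fell (median 0.47, adjusted p = 0.0385, and 0.876 with an estimated correlation), with CYR61 at 2.83, ETV5 at 2.27 and EGR3 at -3.04.

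The lipid lists of the study did not pass the set test in this comparison. Phosphatidylserine and phospholipid synthesis had 13 rose and 11 fell of 34 (median 0.01, set test adjusted p = 0.929), with ETNK2 at -4.58, MBOAT1 at -2.09, AGPAT2 at -1.24 and LPIN1 at 1.37. Phosphatidylserine exposure had 9 rose and 8 fell of 22 (median 0.03, set test adjusted p = 0.772), with the scramblases PLSCR4 (0 counts in B2, at least 921-fold lower) and PLSCR1 (-2.67), the flippase ATP8B2 (-2.80) and PRELID1 (2.05). Fatty acid synthesis had 11 rose and 7 fell of 22 (median 0.28, set test adjusted p = 0.0717), with ELOVL6 at 3.45, ACSL4 at 2.10 and ACSL5 at -2.83. Of nuclear respiratory chain genes, 13 rose and 28 fell of 68 (median -0.17, set test adjusted p = 0.772), and of tricarboxylic acid cycle genes, 6 rose and 8 fell of 21 (median -0.19, set test adjusted p = 0.962). Hypoxia genes had 14 rose and 6 fell of 24 (median 0.47, set test adjusted p = 0.676), with CA12 at -9.48 and LOX at -5.89, and endoplasmic reticulum chaperones had 12 rose and 9 fell of 26 (median 0.10, set test adjusted p = 0.325). Of p53 targets, 16 rose and 7 fell of 29 (median 0.49, set test adjusted p = 0.184), with TP53INP1 at -2.94. Of NF-kappaB targets, 12 rose and 17 fell of 36 (median 0.01, set test adjusted p = 0.772), with LCN2 at -7.68 and CCL20 at -6.23. Extracellular matrix genes had 15 rose and 21 fell of 44 (median -0.22, set test adjusted p = 0.629), with the protease MMP7 at -11.59 and COL5A1 at -9.57.

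The other lists also stayed short of the threshold in B2 against CC. NRF2 targets had 11 rose and 12 fell of 32 (median -0.12, set test adjusted p = 0.911), with ALDH3A1 at -9.42. YAP targets had 17 rose and 7 fell of 30 (median 0.43, set test adjusted p = 0.297), with FSTL1 at -7.99. Ribosomal proteins had 28 rose and 10 fell of 77 (median 0.09, set test adjusted p = 0.105), with RPSA at 1.65. Lysosome genes had 10 rose and 18 fell of 39 (median -0.14, set test adjusted p = 0.184), with CTSL at 0 counts in B2 and 71.7 ± 5.71 CPM in CC. Heat shock genes had 4 rose and 6 fell of 22 (median -0.13, set test adjusted p = 0.929), and metallothioneins had 2 rose and 3 fell of 6 (median -0.10, set test adjusted p = 0.911). Apoptosis regulators had 13 rose and 14 fell of 36 (median 0.15, set test adjusted p = 0.772), with TNFSF10 at -5.60 and PMAIP1 at 2.78. Histones, a sign of how RNA was selected, had 3 rose and 9 fell of 15 (median -0.56, set test adjusted p = 0.629), and nuclear retained RNAs, a sign of RNA quality, had 4 rose and 5 fell of 12 (median 0.07, set test adjusted p = 0.920), with NEAT1 at -1.58 and MALAT1 at -1.17. The leukocyte and endothelial lists had 4 tested members each, too few for a set test. Of the leukocyte markers 3 fell, CD14 by -6.45, and of the endothelial markers 2 rose and 1 fell. The mean had the opposite sign to the median for phospholipid synthesis, phosphatidylserine exposure, fatty acid synthesis, hypoxia, NF-kappaB, YAP, apoptosis and nuclear retained RNAs. The test direction was opposite to the median for the tricarboxylic acid cycle, NF-kappaB, NRF2 and nuclear retained RNAs.

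By the edgeR test, 13225 of 18188 genes (72.7%) were called between B2 and CC, 6155 higher and 7070 lower in B2, and 6750 of them changed at least 2-fold (2594 higher, 4156 lower). Of the 32 lists, 13 passed, 7 up and 6 down, and with an estimated correlation none of the 13 did (lowest adjusted p = 0.524). By fry 25 of the 32 lists passed. Of 1024 list members, 778 were called over all genes and 779 adjusted over the list alone. Library size alone as scaling moved the median of all genes by 0.12 on the log2 scale, and no list that passed changed direction with it. With that scaling 7084 genes were called higher and 6303 lower in B2, so which direction held more genes depended on the scaling. Of the lists that did not pass, the medians of phospholipid synthesis and NF-kappaB changed sign with RLE scaling, and that of metallothioneins with library size only. The ATF4 list lost its call under the stricter filter (adjusted p = 0.0539) and without B2-5 (0.0537), CC-2 (0.0865), CC-3 (0.0504) or CC-5 (0.0540).

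**Figure D2:**
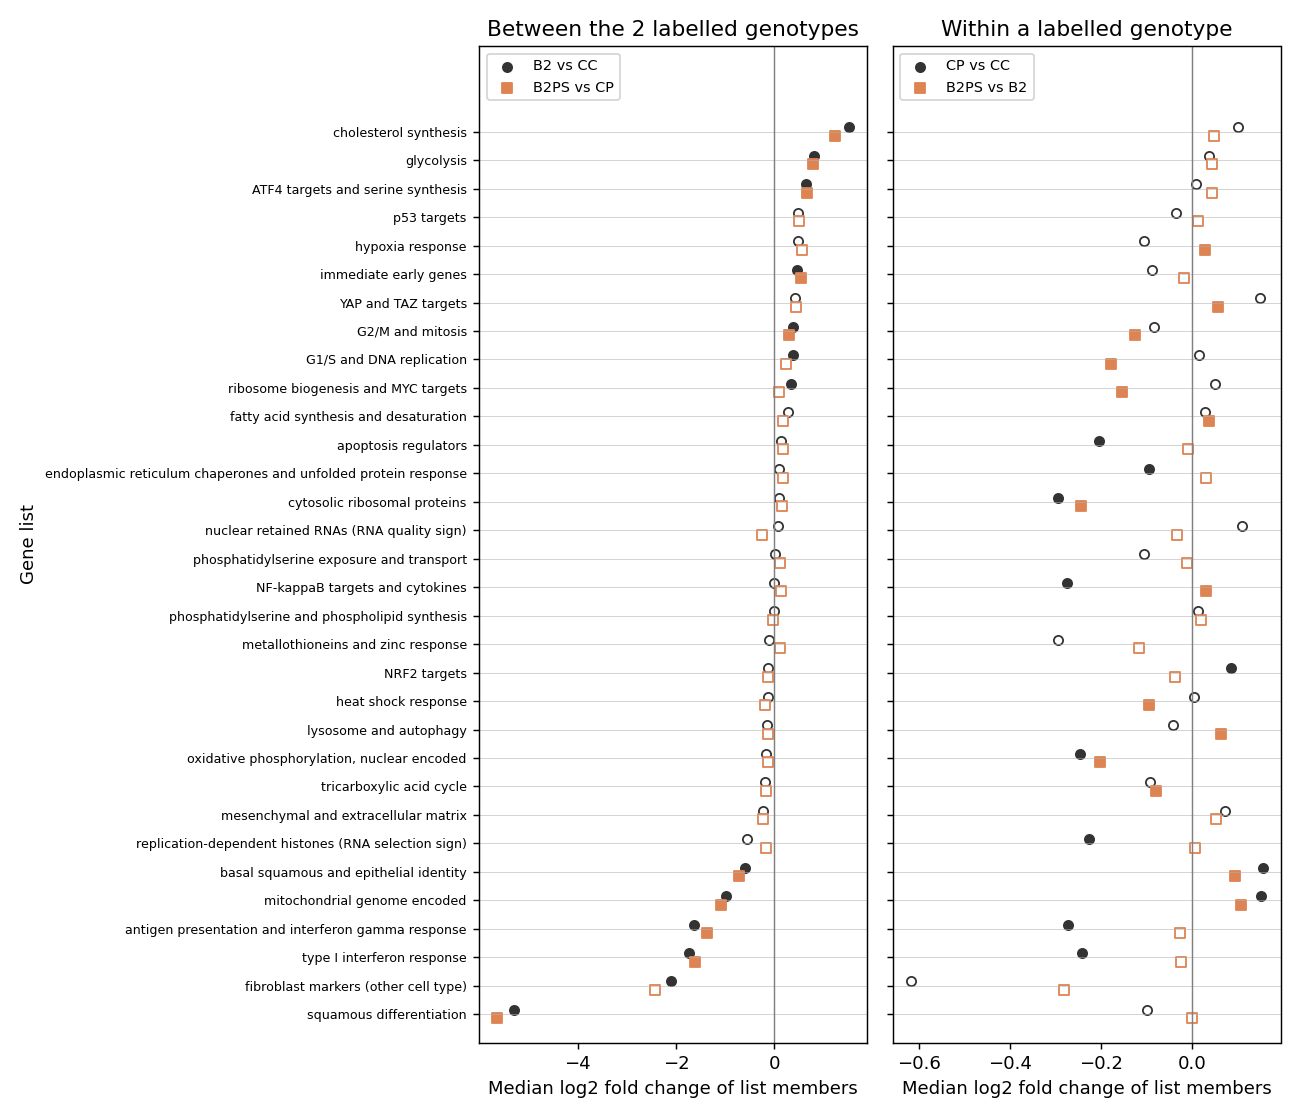
Median log2 fold change of the members of each tested gene list in the 4 pairwise comparisons, on linear axes that differ between the panels, with filled markers where the set test passed. The squamous differentiation list lay at -5.29 for B2 against CC and -5.64 for B2PS against CP, while medians within a genotype label spanned a narrower range.

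Comparing B2PS with CP asks the same question of the genotype labels with the other pair of codes. By the set test, interferon (36 of 42 members fell), antigen presentation (28 of 34) and squamous differentiation genes (50 of 54) were lower in B2PS. Glycolysis genes were higher (15 of 23 rose, 4 fell), and no list passed with an estimated correlation (lowest adjusted p = 0.826). CALML3 was 0.639 ± 0.298 CPM in B2PS and 31.7 ± 7.81 CPM in CP (log2 fold change -5.63, SE 0.32, adjusted p = 2.0e-13), and OTUB1 was 96.1 ± 4.89 and 211 ± 10.9 CPM (log2 fold change -1.13, SE 0.06, adjusted p = 5.8e-14). PTDSS1 was 93.0 ± 3.89 and 106 ± 12.5 CPM (log2 fold change -0.20, SE 0.08, adjusted p = 0.0273), a call that held in 4 of 10 fits with a library left out, over adjusted p from 0.00375 to 0.106. It was lost without B2PS-2 (0.0819), B2PS-3 (0.0886), B2PS-5 (0.0902), CP-2 (0.0745), CP-3 (0.0520) or CP-4 (0.106), with library size only (0.386) and with no filter (0.148). PTDSS2 differed by -0.14 ± 0.08 (adjusted p = 0.106).

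The largest falls in B2PS were of GJB6, PTPRZ1, HTATIP2, SPTSSB and WFDC2, each with 0 counts in B2PS. Their CP levels were 427 ± 83.1, 420.0 ± 28.5, 121 ± 10.2, 119 ± 13.0 and 98.8 ± 25.003 CPM, so that GJB6 was at least 13058-fold and PTPRZ1, a receptor phosphatase, at least 12856-fold lower. TXNIP and SOSTDC1 had 3 counts each in B2PS against 2073 ± 258 and 746 ± 162 CPM in CP. The keratin KRT4 and EFEMP1 had 1 count each against 326 ± 141 and 224 ± 23.0 CPM, and KRT1 fell from 3439 ± 1049.7 to 0.0670 ± 0.0997 CPM (log2 fold change -15.52). The largest rises included MAGEA12 (67.6 ± 7.45 CPM), ZNF680 (28.7 ± 3.04 CPM), PSPHP1 (22.6 ± 3.11 CPM), FOXR2 (20.3 ± 0.886 CPM) and ZFP30 (18.7 ± 3.32 CPM), each with 0 counts in CP. ZBED9 (18.5 ± 1.93 CPM), ZNF607 (12.3 ± 2.17 CPM) and SMIM19 (13.0 ± 1.66 CPM) also had 0 counts in CP. SLC2A3 had 317 ± 43.9 CPM against 3 counts, and SLC20A2 80.4 ± 3.18 CPM against 1 count. SMIM19 starts at 42541155 on chromosome 8, inside the end of SLC20A2 at 42541926, and the strand setting of the counts is not given. The 20 adjusted p-values were at most 4.7e-12.

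In B2PS against CP, interferon genes had 36 of 42 members that fell and 3 that rose (median -1.61, adjusted p = 8.7e-16, and 0.826 with an estimated correlation), with IFI27 at -9.18 and MX2 at -8.46. Antigen presentation had 28 of 34 that fell and 6 that rose (median -1.37, adjusted p = 4.3e-05, and 0.826 with an estimated correlation), with HLA-DRA at -11.05 and CD74 at -9.12. Squamous differentiation had 50 of 54 that fell and 1 that rose (median -5.64, adjusted p = 2.9e-11, and 0.826 with an estimated correlation). Basal squamous genes had 27 of 37 that fell and 8 that rose (median -0.72, adjusted p = 0.0374, and 0.889 with an estimated correlation; without B2PS-1, adjusted p = 0.0543), with CLDN1 at -12.25. The 13 mitochondrially encoded genes fell (median -1.08, adjusted p = 0.0132, and 0.917 with an estimated correlation), beside a mitochondrial share of counts of 3.73% ± 0.299 in B2PS and 6.61% ± 0.323 in CP. Glycolysis had 15 of 23 that rose and 4 that fell (median 0.79, adjusted p = 6.9e-04, and 0.826 with an estimated correlation), with ENO2 at 3.73 and HK2 at 2.20. Cholesterol synthesis had 19 of 25 that rose and 5 that fell (median 1.24, adjusted p = 0.0179, and 0.932 with an estimated correlation), and its mean of -0.10 was opposite in sign. ATF4 targets had 17 of 31 that rose and 9 that fell (median 0.67, adjusted p = 0.0431, and 0.826 with an estimated correlation), a call lost under the stricter filter (0.0550) and without CP-5 (0.0539). G2/M genes had 24 of 43 that rose and 3 that fell (median 0.29, adjusted p = 0.0451, and 0.990 with an estimated correlation), a call lost under the stricter filter (0.0565), with the replicate number as a block (0.0519) and without B2PS-1 (0.0631), B2PS-4 (0.0577), CP-3 (0.0598) or CP-5 (0.0539). Immediate early genes had 20 of 32 that rose and 6 that fell (median 0.54, adjusted p = 0.0315, and 0.889 with an estimated correlation), with ATF3 at 3.76 and KLF6 at 2.20.

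The edgeR test called 13286 of 18188 genes (73.0%) between B2PS and CP, 6017 higher and 7269 lower, of which 6752 changed at least 2-fold. Of the 32 lists 10 passed, 5 up and 5 down, none of them with an estimated correlation (lowest adjusted p = 0.826), and fry passed 26. Lists that passed in B2 against CC but not here were G1/S (median 0.24, set test adjusted p = 0.0833), ribosome biogenesis (0.09, 0.088) and fibroblast markers (-2.42, 0.0652). Adjusted over the list alone 779 members were called, and over all genes 784. Library size alone as scaling moved the median of all genes by 0.12, and no list that passed changed direction with it. Under it 6949 genes were called higher and 6424 lower in B2PS, so here too the balance of directions depended on the scaling. The genotype differences of both code pairs, which share no library, had Pearson r 0.982 and Spearman rho 0.966 across genes, which are not independent replicates. Of 12079 genes called in both, 12074 had the same sign. Of these, 5496 rose and 6578 fell, where independent calls would give 2036 and 2826.

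**Figure D3:**
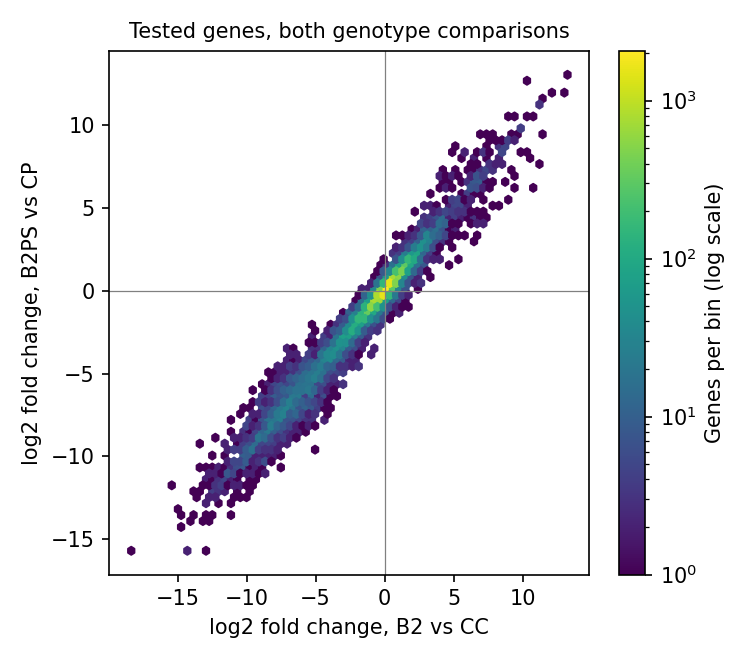
Log2 fold changes of 18188 genes between the genotype labels, with B2 against CC on the x axis, B2PS against CP on the y axis and the number of genes per hexagon as color on a log scale. These genotype differences lay along a line (r 0.982). The title code differences, which are not plotted, had r 0.094 across genes.

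Comparing CP with CC asks what differed between the title codes in control-labelled cells. edgeR called 0 genes, with 3600 at an unadjusted p under 0.05, while DESeq2 called 269 and edgeR with no filter 249, B2M among them in both. By the set test, ribosomal protein, respiratory chain, interferon, antigen presentation and NF-kappaB genes lay lower in CP, by medians of -0.24 to -0.29, and none of these lists passed with an estimated correlation (lowest adjusted p = 0.557). B2M, the light chain of class I antigen presentation, was 2763 ± 533 CPM in CP and 4263 ± 722 CPM in CC, a log2 difference of -0.63 ± 0.18 that missed the threshold (adjusted p = 0.134). CALML3 differed by 0.15 ± 0.22 (0.759), OTUB1 by 0.01 ± 0.06 (0.943), PTDSS1 by 0.16 ± 0.08 (0.265) and PTDSS2 by 0.17 ± 0.08 (0.251), as log2 ± SE with adjusted p.

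For CP against CC, 11 of 32 lists passed, 3 up and 8 down, none with an estimated correlation. The ribosomal protein list (median -0.29, adjusted p = 1.9e-13, and 0.637 with an estimated correlation) included RPL13A at -0.34 and RPL4 at -0.26, neither of which passed alone. The respiratory chain list followed (median -0.25, adjusted p = 6.3e-08, and 0.637 with an estimated correlation). The interferon list (median -0.24, adjusted p = 6.3e-08, and 0.557 with an estimated correlation) had 1 member that fell adjusted over the list alone, and IFI27 was at -0.43. Antigen presentation (median -0.27, adjusted p = 3.5e-07, and 0.557 with an estimated correlation) had 8 members that fell adjusted over the list alone, and NF-kappaB targets (median -0.28, adjusted p = 2.1e-05, and 0.557 with an estimated correlation) had 12. The NF-kappaB difference in list mean went from -0.401 to -0.243 without CC-2, which stood apart from the other CC libraries, and the set test then gave an adjusted p = 0.00871. The histone list, fixed as a sign of how RNA was selected (median -0.23, adjusted p = 0.0247, and 0.637 with an estimated correlation), apoptosis regulators (median -0.20, adjusted p = 0.0203, and 0.557 with an estimated correlation; 1 rose and 3 fell over the list alone) and endoplasmic reticulum chaperones (median -0.10, adjusted p = 0.0247, and 0.596 with an estimated correlation) were lower. The mitochondrially encoded genes (median 0.15, adjusted p = 0.00407, and 0.637 with an estimated correlation), basal squamous genes (median 0.15, adjusted p = 0.0162, and 0.637 with an estimated correlation) and NRF2 targets (median 0.08, adjusted p = 0.0209, and 0.690 with an estimated correlation; 7 rose over the list alone) were higher. With library size only, the chaperone median was -0.05 and the NRF2 median 0.13. Without CC-2 the chaperone (adjusted p = 0.0555), apoptosis (0.0536), histone (0.0559), basal (0.0685) and NRF2 (0.0555) calls were lost. The chaperone call was also lost without CC-3 (0.0829) or CP-4 (0.0779), the apoptosis call without CP-4 (0.0779), and the histone call without CC-3 (0.0548), CP-3 (0.0929) or CP-4 (0.0779). The mitochondrial call was lost without CC-4 (0.126), the basal call without CP-3 (0.0817), and the NRF2 call without CC-3 (0.0583), CP-1 (0.138) or CP-4 (0.434).

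The lists on phosphatidylserine gave little in CP against CC. Phospholipid synthesis had a median of 0.01 (adjusted p = 0.951), with PCYT1A at -0.02. Phosphatidylserine exposure had a median of -0.11 (adjusted p = 0.126), with TMEM30A at -0.20 and PRELID3B at -0.45 (adjusted p = 0.134). Of fatty acid synthesis genes, FASN was at 0.50 (adjusted p = 0.134) and SCD at 0.57 (adjusted p = 0.201), with a list median of 0.03 (adjusted p = 0.140). The fibroblast marker LUM was at -0.77 (adjusted p = 0.134), in a list with a median of -0.62 (adjusted p = 0.109) and 3 members that fell adjusted over the list alone. Over all lists, 52 members were called adjusted over the list alone and 0 over all genes. The features that the authors left without a gene symbol held 0.382% ± 0.0321 of counts in CP and 0.317% ± 0.0164 in CC (exact permutation test, two-sided, p = 0.00794, the smallest possible; adjusted p = 0.0190 over 24 library tests).

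edgeR called 0 of 18188 genes between CP and CC (lowest adjusted p = 0.0708), and 3600 had an unadjusted p under 0.05, where 909.4 are expected by chance. DESeq2 called 269 genes, limma-voom 4, edgeR with no filter 249 and with library size only 1. The median SE was 0.115, a 95% half-width of 0.239 on the log2 scale, and the test on simulated data recovered 62.0% of genes seeded at 1.5-fold. Changes below that size were therefore often not detectable with these libraries.

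Comparing B2PS with B2 asks the same of the title code in cells labelled OTUB2-overexpressing. edgeR and DESeq2 called 0 genes, with 1122 at an unadjusted p under 0.05 by edgeR. By the set test, ribosomal protein, respiratory chain, DNA replication, mitosis and ribosome biogenesis genes lay lower in B2PS, and none of these lists passed with an estimated correlation (adjusted p from 0.593 to 0.707). CALML3 differed by -0.32 ± 0.47 (adjusted p = 0.919), OTUB1 by -0.04 ± 0.06 (0.926), PTDSS1 by 0.00 ± 0.08 (1.00) and PTDSS2 by -0.01 ± 0.08 (1.00), as log2 ± SE. B2M was 1386 ± 155 CPM in B2PS and 1636 ± 535 CPM in B2 (adjusted p = 0.822).

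For B2PS against B2, 14 of 32 lists passed, 7 up and 7 down. With an estimated correlation the lowest adjusted p was 0.593, shared by 13 of the 14, and it was 0.707 for G2/M. Lower were ribosomal proteins (median -0.24, adjusted p = 8.1e-19), the respiratory chain (-0.20, 2.7e-15), G1/S (-0.18, 1.8e-10), ribosome biogenesis (-0.15, 3.2e-09) and G2/M (-0.13, 3.7e-06). RPL13A was at -0.23, NPM1 at -0.35 and MCM3 at -0.18, none of them called. Basal squamous (0.09, 1.7e-04) and lysosome genes (0.06, 1.7e-04) were higher. These 7 held with each library left out, by the set test at the preset correlation. Between libraries, B2PS minus B2 in list means gave exact permutation p = 0.214 for ribosomal proteins, 0.151 for the respiratory chain and 0.206 for G1/S. The tricarboxylic acid cycle list (-0.08, 0.00247) was lost without B2-1 (0.0672), the mitochondrially encoded list (0.11, 0.00247) without B2-2 (0.0534) and the YAP list (0.06, 0.00476) without B2-2 (0.0970). Heat shock (-0.10, 0.0113), with HSPA8 at -0.44, was lost without B2-1 (0.0672), B2-3 (0.0637), B2-5 (0.0568), B2PS-3 (0.0529) or B2PS-5 (0.0596). Fatty acid synthesis (0.04, 0.0319) was lost without B2-4 (0.334), B2PS-1 (0.0676) or B2PS-4 (0.172). Hypoxia (0.03, 0.0385) was lost with RLE scaling (0.0524) and without B2-1 (0.733, reversed), B2-2 (0.107), B2-5 (0.0986), B2PS-1 (0.0751), B2PS-4 (0.312) or B2PS-5 (0.0526). NF-kappaB (0.03, 0.0335) was lost with RLE scaling (0.0562) and without B2-1 (0.148), B2-2 (0.131), B2-3 (0.309), B2PS-1 (0.0601), B2PS-3 (0.0863) or B2PS-5 (0.127).

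edgeR called 0 of 18188 genes between B2PS and B2 (lowest adjusted p = 0.783), and 1122 had an unadjusted p under 0.05 where 909.4 are expected by chance. DESeq2 and limma-voom also called 0, and 1 gene was called without B2PS-4. Adjusted over the list alone, 0 list members were called. The median 95% half-width was 0.233, and 68.0% of genes seeded at 1.5-fold were recovered on simulated data. Phospholipid synthesis had a median of 0.02 (adjusted p = 0.696) and phosphatidylserine exposure a median of -0.01 (adjusted p = 0.920), which was 0.02 with library size only. That scaling moved the median of all genes by 0.04 and changed the direction of no list that passed. Some medians moved by over 1.5 times with it, to 0.07 for hypoxia, 0.07 for NF-kappaB, 0.10 for YAP targets, 0.08 for fatty acid synthesis and 0.11 for lysosome. The medians of the tricarboxylic acid cycle (-0.04), heat shock (-0.05) and G2/M (-0.08) came closer to 0. With RLE scaling, hypoxia (0.05), NF-kappaB (0.05) and fatty acid synthesis (0.06) moved by over 1.5 times.

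The interaction asks whether the title code difference itself differed between the genotype labels. It takes B2PS minus B2 and CP minus CC as the same contrast, which no label states. edgeR called 0 genes, and the set test passed 3 immune lists, none of them with an estimated correlation (lowest adjusted p = 0.368). These lists lay lower in CP than in CC, and in B2PS against B2 their medians were -0.03 for interferon, -0.03 for antigen presentation and 0.03 for NF-kappaB, the first pair changing to 0.02 and 0.02 with library size only. NF-kappaB targets had a median difference of 0.39, antigen presentation of 0.24 and interferon genes of 0.20 on the log2 scale. The mean log2 level was already lower in B2 than in CC, at 4.32 against 7.55 for interferon and 2.89 against 4.08 for NF-kappaB. Members with few or no counts in B2 can hardly fall further, and how far this shaped the interaction was not tested. Without CC-2, CP minus CC in the NF-kappaB list mean went from -0.401 to -0.243. G1/S and ribosome biogenesis genes both had medians of -0.21. Of the 32 lists 11 passed, 7 up and 4 down, none with an estimated correlation (lowest adjusted p = 0.368). B2M had an interaction of 0.39 ± 0.25 (adjusted p = 0.888), CALML3 of -0.47 ± 0.52 (0.946), OTUB1 of -0.05 ± 0.09 (0.978), PTDSS1 of -0.15 ± 0.11 (0.902), PTDSS2 of -0.18 ± 0.11 (0.885) and OTUB2 of 0.29 ± 0.32 (0.945). edgeR called 0 genes, with 1072 at an unadjusted p under 0.05, DESeq2 called 0 and edgeR with no filter 2. Adjusted over the list alone, 3 members were called, 2 of the YAP list and 1 of the heat shock list. The median half-width of an interaction was 0.337.

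Across genes, the title code differences in the control-labelled and the OTUB2-labelled libraries had Pearson r 0.094 and Spearman rho 0.271. Genotype and title code differences that share the CC libraries, B2 against CC and CP against CC, had r 0.153 from the fit and 0.173 from mean log2 CPM. Simulated unchanged groups against shared controls gave r 0.522, with a covariance of 0.0227 against 0.0942 observed. The simulation gave B2 and CP the CC means, while 72.7% of genes were called between B2 and CC. The simulated r is therefore not comparable with the observed r. With the CC libraries split between the comparisons, r was 0.0795 and 0.161.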

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

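The OTUB2 interval test, the thinning, and the regrouping and single-library tests of list means below were chosen only after the result was seen.

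In the libraries labelled OTUB2-overexpressing, 13225 genes differed between B2 and CC while OTUB2 was not higher. The higher of its upper 95% limits, from B2PS against CP, was 0.219 on the log2 scale, which argues against overexpression of OTUB2 counted from its reference sequence, and thinning all libraries to the smallest total still gave 12551 called genes, which argues against depth as the source. Of 100 splits of the 10 libraries only the real one gave as many genes (highest other 5341). For B2PS against CP it was likewise 1 of 100 (13286, highest other 0). A chance division of the libraries was therefore unlikely for both. The splits do not cover chance between cultures or clones, since the labels do not say whether the libraries of a group came from separate cultures. Medians over 258 windows of 50 neighbouring genes had an SD of 0.415 (highest of 1000 shuffles 0.156). Of these windows 41 lay beyond 0.5, against 0 in each title code comparison. A spread wider than every shuffle was the prediction for cells of a different origin or clone. CP against CC (0.0791 against 0.0408) and B2PS against B2 (0.0371 against 0.0271) also exceeded their shuffles, with a smaller spread, as co-regulated neighbours could cause. The test alone therefore cannot decide, and cells of a different origin or clone remain open. An exchange of the genotype labels with OTUB2 counted from its reference sequence is bounded by the lower 95% limits of -1.02 and -0.70, while an exchange, or an effect of the label as given, with a coding sequence that these counts do not see was not tested and stays open.

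In CP against CC, 3600 genes had an unadjusted p under 0.05 and ribosomal protein and respiratory chain genes lay lower. The ribosomal protein median of -0.294 (bootstrap interval over its 77 members -0.337 to -0.260) was -0.285 after the trend with gene length was removed and -0.299 after the trend with GC content was removed, which argues against both as the whole source. That interval resampled genes and covers no spread between libraries. Within groups, list means of ribosomal protein and respiratory chain genes correlated over 20 libraries (Pearson r 0.89, Spearman rho 0.898, permutation p = 1e-05 each, the smallest these permutations can give; r 0.898 without B2-1 and CC-3), so variation between libraries that both lists share is a candidate explanation. Of 100 splits of the 10 libraries 2, the real one included, gave as many genes at that unadjusted p (highest other 4131). Since another split gave more genes than the real one, a chance division was unlikely for this count but not excluded. It was not excluded for the lists either, whose means gave exact permutation p = 0.0556 (ribosomal protein) and 0.0476 (respiratory chain) for CP minus CC, both 0.0926 adjusted over 5 lists. An effect of the title code in control-labelled cells stays open as the biological explanation. A difference in RNA selection stays open as a technical one, of which the histone list is a sign (median -0.23). That histone call was lost without CC-2, CC-3, CP-3 or CP-4. In B2PS against B2, ribosomal proteins also lay lower (median -0.24), while the histone median was 0.01 (set test adjusted p = 0.141).

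For CP against CC the count of 0 genes at the adjusted threshold was reached by 100 of 100 splits (highest other 85), for B2PS against B2 by 100 of 100 (real 0, highest other 1080) and for the interaction by 100 of 100 (real 0, highest other 3). With a real count of 0 every split gives as many, so these counts say nothing about chance. The split of the B2 and B2PS libraries that calls 1080 genes points to a structure of these samples whose nature was not tested, and with it 10 splits other than the real one were above 0 (median 0).

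Single libraries stood apart from the other 4 of their group for 7 of 116 groups of values tested, where about 1 in 20, or 5.8, is reached by chance. ZC4H2 was 11.99 CPM in B2-1 (others 15.97 to 17.51) and 18.73 CPM in B2PS-4 (others 14.1 to 15.19). S100A7 was 515.2 CPM in CP-1 (others 193.6 to 285.8), SLC2A3 was 394.8 CPM in B2PS-4 (others 290.3 to 302.1) and SMIM19 was 10.08 CPM in B2PS-5 (others 13.48 to 14.1). B2PS-4 had 24422 genes with a count (others 25370 to 25681). The mean log2 level of NF-kappaB targets was 4.708 in CC-2 (others 3.871 to 3.994), and without that library CP minus CC went from -0.401 to -0.243.

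The title code difference differed between genotype labels for 11 lists by the set test of the interaction, and none held with an estimated correlation (lowest adjusted p = 0.368). That difference, not the level itself, was higher in the OTUB2-labelled than in the control-labelled libraries for NF-kappaB targets (adjusted p = 8.49e-09), interferon response (1.4e-07), antigen presentation (4.3e-07), histones, a sign of RNA selection (0.000346), endoplasmic reticulum chaperones (0.000511), lysosome (0.00316) and apoptosis regulators (0.0284). The interaction medians of these lists were 0.39, 0.20, 0.24, 0.28, 0.10, 0.14 and 0.09. The NF-kappaB and interferon lists already lay lower in B2 than in CC, which may limit a further fall and was not tested. The title code difference was lower for ribosome biogenesis (5.79e-09, median -0.21), G1/S (4.59e-08, -0.21), heat shock (0.0385, -0.09) and NRF2 targets (0.0482, -0.19). With each library left out in turn, 8 of the 11 held. The apoptosis call was lost without B2-3 (0.0754), CC-2 (0.0821) or CP-4 (0.130). The heat shock call was lost without B2-3 (0.0950), B2-5 (0.102), B2PS-2 (0.102), B2PS-3 (0.0836), B2PS-5 (0.126), CC-2 (0.486), CC-3 (0.0822), CC-5 (0.0722), CP-2 (0.296) or CP-4 (0.0637). The NRF2 call was lost in 13 of 20 such fits, without B2-1 (0.0657), B2-2 (0.165), B2-5 (0.0785), B2PS-2 (0.0742), B2PS-3 (0.0533), B2PS-4 (0.0826), B2PS-5 (0.0511), CC-1 (0.0691), CC-2 (0.134), CC-3 (0.0822), CC-5 (0.0832), CP-1 (0.301) or CP-4 (0.707).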

How the results depend on the processing

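Thinning every library to the smallest total was chosen after seeing the data. Under it 12551, 0, 0, 12566 and 0 genes were called for B2 against CC, CP against CC, B2PS against B2, B2PS against CP and the interaction. Of 10650 values of 526 gene results under alternatives, 10630 kept their direction and side of the threshold, 15 were weaker (PTDSS1 and ENG in B2PS against CP), 5 stronger and 0 reversed. OTUB2 is counted apart, and its B2 against CC call held in 10 of 19 alternatives. RLE scaling kept 157 of 160 list results, the stricter filter 156 and the replicate block 158. With libraries left out, 1774 of 1920 were kept, 74 were weaker, 70 stronger and 2 reversed. An estimated correlation left 0 lists in each of the 5 comparisons, and the estimated correlation was above the preset 0.01 for most lists. fry, which tests balance within a list and not against other genes, passed 25 lists for B2 against CC, 2 for CP against CC, 0 for B2PS against B2, 26 for B2PS against CP and 0 for the interaction. It reversed the phosphatidylserine and phospholipid synthesis list, with a signed -log10 p of -3.593 for B2 against CC (adjusted p = 0.00048) and -3.537 for B2PS against CP (adjusted p = 0.000546). With a 2-fold minimum, 6750 and 6752 genes passed for the genotype comparisons, a stricter rule by its construction.

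For CP against CC, the gene count was 1 with library size only, 249 with no filter, 4 by limma-voom, 269 by DESeq2 and 0 to 3 with each library left out (3 without CP-5), and its lists numbered 7 (without CC-2) to 16 (without CP-5). With no filter B2M (adjusted p = 0.019), PRELID3B (0.0372), FASN (0.0356) and LUM (0.00935) were called, and by DESeq2 B2M (0.044). B2PS against B2 gave 0 to 1 genes with each library left out, and the interaction 2 genes with no filter. OTUB2 in B2 against CC was -0.41 with library size only (adjusted p = 0.119), -0.521 with no filter (0.0881) and -0.651 (without B2-4) to -0.412 (without CC-4) with libraries left out (0.0221 to 0.137), where 3 of 10 fits kept the call. The rank correlation of the title code differences was 0.271, against r 0.094. The hypoxia response list of B2PS against B2 ran from -0.298 (without B2-1, adjusted p = 0.733) to 6.268 (without B2-4) as signed -log10 p, and the cytosolic ribosomal proteins list of the interaction from -1.923 (without B2-1, adjusted p = 0.0382) to 4.223 (without CC-3). The cause was not tested for any of these changes. Replicate numbers did not pair the libraries: 30 same-numbered pairs had r from -0.224 to 0.157 (median -0.0134), 3 of them over 0.1, and 5 of 20 libraries correlated best with their own number. With the number as a block, 13038, 0, 0, 13126 and 0 genes were called, and G2/M in B2PS against CP lost its call (0.0519). Alternatives meant for normalized values were not run, since counts were deposited.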

Other observations

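The test of the title codes below was chosen only after the result was seen, and the genes and regions were named after their values were seen.

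A set of 220 genes was near silent in B2 and B2PS (under 0.5 CPM in every library) while at 10 CPM or more in every library of CC and CP, and 16 genes showed the opposite. No gene met these limits in either direction between title codes (0 in each of the 4 sets). NDRG2 was 762 ± 234 and 586 ± 105 CPM in CC and CP, and 0.0576 ± 0.0690 and 0.0905 ± 0.116 CPM in B2 and B2PS. UBB, a polyubiquitin gene, was 303 ± 31.7 and 260.1 ± 18.5 CPM in CC and CP, and 0.187 ± 0.111 and 0.0539 ± 0.0536 CPM in B2 and B2PS. CXCL14, a chemokine, was 308 ± 93.6 CPM in CC and 0.0577 ± 0.0576 CPM in B2, and ALDH1A1, a retinal dehydrogenase, 78.3 ± 11.1 and 0.0477 ± 0.0505 CPM. MGMT, a DNA repair gene, and GSTM3, a glutathione transferase, had 0 counts in B2 and B2PS, against 23.1 ± 2.04 and 25.8 ± 6.23 CPM in CC. The other way, ZNF300 was 50.4 ± 10.6 CPM in B2 and 0.154 ± 0.0888 CPM in CC, MEIS3, a homeobox gene, 24.6 ± 5.12 and 0.0588 ± 0.0619 CPM, and CHRM3, a muscarinic receptor, 18.6 ± 4.54 and 0.144 ± 0.0736 CPM. The keratins KRT5 (4271 ± 921 CPM in B2, 11818 ± 2123 CPM in CC) and KRT14 (2195 ± 403 and 12409 ± 2327 CPM) were abundant in both.

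Windows of 50 neighbouring genes had medians that ran along chromosomes in both genotype comparisons. They lay between -1.87 and 1.63 for B2 against CC and between -1.87 and 1.53 for B2PS against CP. The largest fall thus exceeded the largest rise in each, and the regions named next are only rises. The 7 adjacent windows from 3126916 to 88149885 on chromosome 3 had medians of 0.67 to 1.07 for B2 against CC and of 0.68 to 1.10 for B2PS against CP. The windows from 134465 to 28623112 on chromosome 10 had 1.18 and 1.41, then 1.09 and 1.34, and those from 107928503 to 125090312 on chromosome 11 had 1.55 and 1.63, then 1.505 and 1.53. In these windows the medians of CP against CC lay between -0.10 and 0.07 and those of B2PS against B2 between -0.07 and 0.02. Over all 258 windows, 41 lay beyond 0.5 for B2 against CC and 42 for B2PS against CP, with r 0.983 between their medians.

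Ribosomal protein genes lay lower with the B2PS and CP codes than with B2 and CC, so the code may shift them in both genotype labels. The difference in list mean was -0.215 for B2PS minus B2 (exact permutation p = 0.214) and -0.259 for CP minus CC (exact permutation p = 0.0556). The sum of both gave an exact permutation p = 0.0203 over 63504 regroupings, two-sided, and 0.0506 adjusted over the 5 lists tested. Nuclear-encoded respiratory chain genes gave -0.193 and -0.204, with an exact permutation p = 0.0148 for the sum and 0.0506 adjusted. B2PS minus B2 rests in part on single libraries, being -0.338 without B2-1 and -0.137 without B2-2 for ribosomal protein genes and -0.121 without B2-2 for the respiratory chain. The other lists gave exact permutation p = 0.148 (interferon), 0.197 (NF-kappaB) and 0.366 (G1/S) for the sum, adjusted to 0.246, 0.246 and 0.366. For G1/S, B2PS minus B2 was -0.171 (exact permutation p = 0.206), and it was -0.111 without B2-1 and -0.280 without B2-4. These tests leave a shift by the title code open and do not establish it. The sum also takes the codes B2PS and CP as matching, which no label states.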
